A study of Homo sapiens with 20 samples.

How the data were processed

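Total RNA of 20 prostate tissue samples was hybridised to Affymetrix gene-level arrays, with 10 samples in each of the surgical and incidental groups, taken from the sample titles. Per the submitters' processing notes, the authors made the log2 values with RMA in Affymetrix Expression Console 1.2. The annotation release and the genome build used in the processing are not given in the sources used here, although the deposited descriptions of some probe sets name positions on GRCh37. The deposited series matrix holds log2 values of 53427 probe sets, and the deposited workbook holds the same values with more decimals for 53617 probe sets, 190 of them controls. The values in both agree within 0.005. The deposited workbook also has the authors' ANOVA, with mean log2 values, a ratio and fold per probe set, p-values, and score columns of F and sums of squares, per the file headers. RMA sets arrays to a common distribution, so a change shared by most genes would be removed, and summarising probes reduces the size of changes of dim genes.

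Gene names came from the deposited annotation column, updated through RefSeq names (GRCh38.p14 table, used for names only). One symbol was found for 22094 probe sets, several for 25 and none for 31308. Of those with 1 symbol, 19427 were matched by accession, 1248 by symbol and 523 by synonym, and 896 kept the name in the file. Y-linked genes and XIST, 134 probe sets, were left out. The remaining 22063 probe sets with a symbol were tested, and 31230 probe sets without one were tested separately.

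The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with the group as the only term and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. A gene was counted once. Gene lists, 35 in all, were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean, with adjustment over the lists. They covered stress and early response genes, cell types of the prostate and of neighbouring tissue, immune cells, signalling, metabolism and steroid genes. Permutation tests used 100000 resamples, or 20000 for residuals with a covariate, were two-sided for differences and correlations, and with 100000 resamples can give no p below 1e-05. The design, lists, rule for named genes and most alternatives were fixed before the data were examined.

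Named genes were the 12 with the largest increase and the 12 with the largest decrease among genes past the test (9 qualified as higher), without LOC symbols, open reading frames, small RNAs, pseudogenes and immunoglobulin or T cell receptor segments. Up to 4 members with the smallest p of each list past camera, or with at least 3 members past the test, were added, with FOS, FOSB, JUN, JUNB, JUND and ATF3. The rule gave 72 genes, of which 22 passed. Other genes named in the closing section were chosen after their values were seen, except 15 further skeletal muscle genes chosen after the pattern on 1 array was seen and before their own values were.

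Alternatives were the workbook values, a further quantile normalization, centring on array medians, a filter that kept the 11138 probe sets above the overall median of 4.83 on at least 10 arrays, array weights, the replicate number as a block, luminal and smooth muscle means as covariates, trend and robust moderation, one-way ANOVA, other thresholds, each array left out, and for lists an estimated correlation, fry and all probe sets. Added after seeing the data were the removal of 4 arrays whose mean correlation with the others lay over 3 MAD below the median (surgical replicates 3 and 5, incidental replicates 1 and 7) and a permutation test of list means, and the differences in array median without surgical replicate 3 and in list means without incidental replicate 1. Centring used array medians of the 22063 tested probe sets, while the array medians printed below are over all 53427 probe sets. The labels give no batch or scan date, so no batch was tested.

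On data simulated from the means and residual SDs of the 22063 probe sets, with 50 probe sets changed per size, limma recovered 28% of changes of 0.5 log2, 74% of changes of 1, 96% of changes of 1.5 and 98% of changes of 2, with 4 false calls and 0 wrong signs. The noise was drawn independently per probe set, so these rates need not hold on arrays where genes vary together. In simulated uncorrelated data, camera recovered 3 of 3 shifted lists and called 0 of 32 others. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.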

Results

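Gene expression was measured in human prostate tissue with benign prostatic hyperplasia (BPH), a non-malignant enlargement of the gland. There were 20 arrays, 10 of BPH that the labels call surgical and 10 of BPH that they call incidental, and the design text gives a surgical distinction as the basis of the cohorts. The question addressed was which genes differ in tissue level between the groups. All values are RMA log2 values, and differences are surgical minus incidental. The labels do not say that each array came from a separate donor, so p-values measure the spread between these samples. The median of an array over all 53427 probe sets lay between 3.34 and 3.72. It averaged 3.48 ± 0.09 (SD, n = 10) on surgical arrays and 3.41 ± 0.03 (SD, n = 10) on incidental arrays, a difference of 0.07 (two-sided permutation test, p = 0.00361, Benjamini-Hochberg adjusted p = 0.0217 over 6 array measures). Without surgical replicate 3, the highest at 3.72, the difference was 0.04 (adjusted p = 0.042). The closest pair of arrays correlated at r = 0.975, so no array was a copy of another. The number of arrays limits the precision of every value.

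Several heat shock and immediate-early genes, among them ATF3, EGR1, JUN and DNAJB1, were higher in surgical BPH, and the smooth muscle genes DES, KCNMB1 and ACTA2 were lower. The lists of heat shock, immediate-early and smooth muscle genes passed camera at a preset correlation and each had an adjusted p = 0.156 with an estimated correlation, which does not pass. For the immediate-early list, fry (adjusted p = 0.0702) and the permutation of list means (adjusted p = 0.0939) did not pass either. Of 21374 genes, 62 differed (limma with Benjamini-Hochberg adjustment over 22063 probe sets, adjusted p under 0.05), of which 10 were higher and 52 lower in surgical samples. Among genes past the test, the largest increase was in ATF3, a stress-induced transcription factor (probe set 16677278), at 8.28 ± 1.22 (SD, n = 10) against 6.19 ± 0.65, a log2 difference of 2.10 (SE 0.402, 4.28-fold, adjusted p = 0.0311). All 10 surgical arrays lay above the incidental median. EGR1, a zinc finger transcription factor induced within minutes of a stimulus, rose by 1.77 (SE 0.371, adjusted p = 0.0454) and lay above the incidental median on 9 of 10 surgical arrays. Its call ended, with differences of 1.77, 1.87 and 1.76, after quantile normalization (adjusted p = 0.0685), after centring on array medians (0.0556) and without the 4 arrays standing apart (0.0631). Without those arrays ATF3 (2.14) and PPP1R15A (1.85) did not pass either (adjusted p = 0.0607 for each). PPP1R15A, which directs dephosphorylation of the translation factor eIF2 alpha, rose by 1.74 (SE 0.351, adjusted p = 0.0355). JUN, a subunit of the AP-1 transcription factor, rose from 9.03 ± 0.44 to 10.29 ± 0.65 (SD, n = 10 each; log2 difference 1.27, adjusted p = 0.0311).

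The chaperones that rose were DNAJB1 (log2 difference 1.77), HSPA1B (1.59), HSPA1A (1.56), HSPA6 (1.35) and HSPD1 (1.21), with limma adjusted p-values from 0.0311 to 0.048. After centring on array medians HSPA6 differed by 1.44 and did not pass (adjusted p = 0.0556). DNAJB1 is a co-chaperone of HSP70, HSPA1A, HSPA1B and HSPA6 are inducible HSP70 proteins, and HSPD1 is the mitochondrial chaperonin. HSPA1A and HSPA1B are near-identical copies, so the split between them is uncertain. In the list of 17 measured heat shock and chaperone genes, 5 rose over all genes tested, none fell, and 12 were higher when adjusted over the list alone. The list median was 0.74 higher in surgical samples, and the list passed camera at a preset correlation (adjusted p = 3.16e-18). Its adjusted p = 0.156 with an estimated correlation, which ends that call, and fry gave an adjusted p = 0.0202. On all 10 surgical arrays the list mean lay above the incidental median.

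Of 35 measured immediate-early genes outside AP-1, 33 had a difference above 0. Only EGR1 and PPP1R15A passed over all genes, and 23 were higher when adjusted over the list alone. The list median was 0.92 (camera adjusted p = 3.32e-21, and adjusted p = 0.156 with an estimated correlation). The list mean lay above the incidental median on 8 of 10 surgical arrays, and below it on surgical replicates 6 (6.33) and 9 (6.28). EGR3 differed by 1.36 and NR4A1 by 1.48, each with an adjusted p = 0.0614, which does not pass. Of 16 measured AP-1 subunits, ATF3 and JUN rose over all genes, and 7 were higher when adjusted over the list alone. This list follows what is known of the published study of these samples, so it is not independent evidence of a direction. FOS differed by 1.74 (SE 0.381, adjusted p = 0.0518) and FOSB by 2.20 (SE 0.666, adjusted p = 0.126), and neither passed. JUNB differed by 1.06 (adjusted p = 0.212) and JUND by 0.92 (adjusted p = 0.134), also without passing. The AP-1 list median was 0.74 (camera adjusted p = 8.81e-10, and adjusted p = 0.156 with an estimated correlation). The AP-1 mean too lay above the incidental median on 8 of 10 surgical arrays, with surgical replicates 6 (6.07) and 9 (6.10) below it. None of 24 genes regulated by NF-kB, which are cytokines and chemokines with others such as SOD2, SELE, ICAM1 and NFKBIA, passed, over all genes or adjusted over the list alone, although 23 had a difference above 0. CXCL8, a chemokine that attracts neutrophils, differed by 1.95 (SE 0.632, adjusted p = 0.149). That list had a median of 0.70 (camera adjusted p = 6.35e-11, and adjusted p = 0.156 with an estimated correlation). Its mean lay above the incidental median on 7 of 10 surgical arrays.

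**Figure D1:**
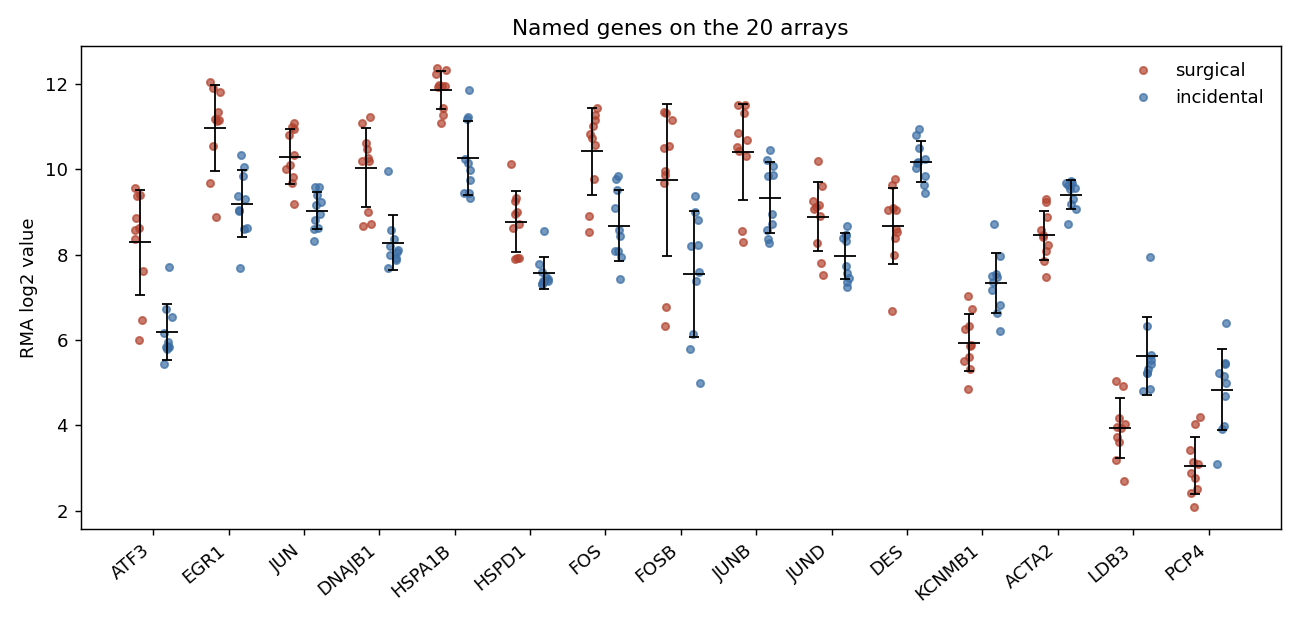
RMA log2 values of 15 named genes, with 1 point per array, 10 surgical and 10 incidental arrays, and black bars for the mean and SD of each group. ATF3 averaged 8.28 on surgical and 6.19 on incidental arrays, DES averaged 8.68 and 10.17, and FOS, FOSB, JUNB and JUND did not pass the test.

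All 19 measured smooth muscle genes had differences below 0. Of these, 3 passed over all genes, namely DES, KCNMB1 and ACTA2, and 16 were lower when adjusted over the list alone. DES, the intermediate filament protein desmin, fell from 10.17 ± 0.48 to 8.68 ± 0.89 (SD, n = 10 each; log2 difference -1.50, SE 0.297, limma adjusted p = 0.0343). KCNMB1, a subunit of the calcium-activated potassium channel of smooth muscle, fell by 1.40 (SE 0.283), and ACTA2, smooth muscle actin, fell by 0.96 (SE 0.203). For each of these genes all 10 surgical arrays lay below the incidental median. None of the 3 passed after quantile normalization or after centring on array medians, where DES differed by -1.52 and -1.40 (adjusted p = 0.0572 and 0.0589), KCNMB1 by -1.27 and -1.31 (0.0875 and 0.0669) and ACTA2 by -0.93 and -0.86 (0.0719 and 0.0829). The list median was -1.11 (camera adjusted p = 1.16e-15, adjusted p = 0.156 with an estimated correlation, fry adjusted p = 0.0202).

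Among named genes past the test and outside that list, large decreases were in KIAA1210 (log2 difference -1.85), CAPN6 (-1.75), TMEM158 (-1.70), LDB3 (-1.70) and HOXD13 (-1.52), with adjusted p-values from 0.0311 to 0.0472. PCP4, which modulates calcium binding by calmodulin, was lower too (adjusted p = 0.0311), and no size is given since it lay below the background probes on 4 of 10 surgical arrays, as KIAA1210 and LDB3 did on 1 each. LDB3 is a Z-disc protein of muscle, and HOXD13 is a homeobox transcription factor of the posterior body axis. DTNA, which encodes the dystrophin partner dystrobrevin alpha, fell by 1.42, and NDP, the secreted Wnt pathway ligand norrin, fell by 1.34. RBFOX3, an RNA splicing factor, fell by 1.36, and TMEM35A, a chaperone of nicotinic acetylcholine receptors, fell by 1.33. HOXD13 and NDP passed after both quantile normalization and centring on array medians, and PCP4 after the first alone. KIAA1210, CAPN6, TMEM158, LDB3, DTNA, RBFOX3 and TMEM35A passed after neither, with differences from -1.78 to -1.21 and adjusted p-values from 0.0525 to 0.0875. Without the 4 arrays standing apart, 6 of the 13 lower named genes past the test still passed. With the luminal and smooth muscle list means as covariates the difference was -0.83 for KIAA1210, -1.25 for CAPN6, -0.67 for TMEM158, -0.59 for LDB3, -0.52 for HOXD13, -0.48 for DTNA, -1.07 for NDP, -0.51 for RBFOX3 and -0.27 for TMEM35A, none of which passed. In incidental replicate 1, which stood apart in skeletal muscle genes, LDB3 was at 7.94 against at most 6.32 on the other incidental arrays.

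At least a 1.5-fold change was reached by 58 of the genes, 10 higher and 48 lower. The counts depended on scaling: after a further quantile normalization 17 genes passed, 10 higher and 7 lower, and after centring each array on its median 16 passed, 9 higher and 7 lower. Over all tested probe sets the median difference was -0.038 as deposited, with 56.4% below 0. That median was 0 after quantile normalization, with 50.1% below 0, and 0.058 after centring, with 40.5% below 0. Centring used the array medians of the tested probe sets, which were therefore lower on average on surgical arrays. Array medians over all probe sets were higher there. One-way ANOVA with Benjamini-Hochberg adjustment called 4 genes, 0 of them higher. The filter on dim values gave 225 genes, 28 higher and 197 lower, and array weights gave 148, 41 higher and 107 lower. With the luminal and smooth muscle list means as covariates, limma called 0 genes (1586 at an unadjusted p under 0.05). Limma also called 0 genes when surgical replicate 1, 2 or 4 or incidental replicate 4, 5, 8 or 10 was left out (2768 to 3127 at an unadjusted p under 0.05). It called 3 without incidental replicate 3, 21 without incidental replicate 9, 26 without incidental replicate 1, 33 without surgical replicate 5, 37 without surgical replicate 3 and 38 without surgical replicate 10 or incidental replicate 2. It called 133 without surgical replicate 6, 192 without surgical replicate 7 and 381 without incidental replicate 7.

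Camera at a preset correlation called 15 of the 35 lists, 12 higher and 3 lower, none of which held with an estimated correlation (8 lists at an unadjusted p under 0.05), and fry called 2. Besides those above, the lists called higher had medians of 0.36 for luminal epithelium, whose mean difference turned below 0 without incidental replicate 1 (-0.06), 0.24 for red blood cells, 0.13 for seminal vesicle and ejaculatory duct, 0.20 for prostate carcinoma, 0.27 for senescence, 0.16 for hypoxia, 0.09 for cytosolic ribosomal proteins and 0.07 for the unfolded protein response. Their adjusted p-values ran from 0.002 to 0.0439 at the preset correlation. Of the 18 measured senescence genes, 5 are also in other lists, with CXCL8, IL6, CXCL1 and IL1A in the NF-kB list. With an estimated correlation the adjusted p was 0.752 for luminal epithelium, ribosomal proteins and the unfolded protein response, 0.188 for red blood cells, 0.156 for seminal vesicle and for carcinoma, 0.479 for senescence and 0.626 for hypoxia. The red blood cell list averaged 2.65 on surgical arrays, below the mean of 2.86 of their background probes. Of its members HBA1 (4.48), HBA2 (3.66), HBM (3.12) and AHSP (3.07) averaged above that background mean there, and the others below it. In the seminal vesicle list SEMG1 (2.00), SEMG2 (1.87), PATE1 (2.08), PATE4 (1.47), CRISP1 (1.89) and CLDN2 (2.83) averaged below it there too. PAX2, MUC6, AKR1B1 and LRRC26 averaged above it. No member of the lists from luminal epithelium to the unfolded protein response passed, over all genes or adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.20 (camera adjusted p = 9e-07, adjusted p = 0.471 with an estimated correlation). Of its 40 measured members none passed over all genes, and COXFA4, NDUFA6 and UQCRC1 were lower when adjusted over the list alone. MHC class II genes had a median of -0.32 (camera adjusted p = 0.0473, adjusted p = 0.752 with an estimated correlation), and HLA-DQB1 alone was lower when adjusted over the list alone. With the luminal and smooth muscle list means as covariates the direction turned for MHC class II (median 0.375). It also turned for ribosomal proteins (-0.09) and the unfolded protein response (-0.073).

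The other 20 lists did not pass camera. Among epithelial and secretory lists the median was 0.22 for androgen-responsive genes (adjusted p = 0.229), 0.26 for basal epithelium (0.0697), -0.05 for club, hillock and urothelial-type epithelium (0.483) and -0.12 for neuroendocrine cells (0.868). Among stromal, vascular and muscle lists the median was -0.26 for fibroblasts and collagen matrix (0.108), 0.13 for endothelium (0.092), -0.45 for nerve and Schwann cells (0.108), and -0.45 for skeletal muscle (0.249). Without incidental replicate 1 the list mean difference went from -0.49 to -0.01 for skeletal muscle and from -0.37 to -0.22 for nerve and Schwann cells. It turned from 0.25 to -0.06 for luminal epithelium, from 0.13 to -0.05 for androgen-responsive genes and from 0.07 to -0.03 for epithelial-mesenchymal transition, and went from 0.20 to 0.02 for basal epithelium and from -0.01 to -0.18 for club, hillock and urothelial-type epithelium. The mean difference widened from 0.11 to 0.20 for endothelium and from -0.09 to -0.15 for cell proliferation. Among immune lists the median over all arrays was -0.27 for interferon response (0.0548), -0.15 for T and NK cells (0.0749), -0.09 for B and plasma cells (0.908), -0.25 for macrophages and monocytes (0.0884), 0.01 for neutrophils (0.712) and -0.12 for mast cells (0.897). It was -0.10 for proliferation (0.733), -0.09 for peptide growth factors (0.65), -0.06 for small nucleolar and spliceosomal RNAs (0.908) and 0.19 for epithelial-mesenchymal transition (0.249). Steroid receptors and metabolism had a median of -0.06 (0.667) and targets of drugs for urinary symptoms -0.20 (0.108), each p-value being camera's adjusted p. For the club, B cell, mast cell and small RNA lists camera's direction was up although the median and mean were below 0. After centring on array medians the median turned above 0 for the club (0.04), B cell (0.01), growth factor (0.00), steroid (0.04) and small RNA (0.04) lists, and after quantile normalization for the club list (0.04).

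**Figure D2:**
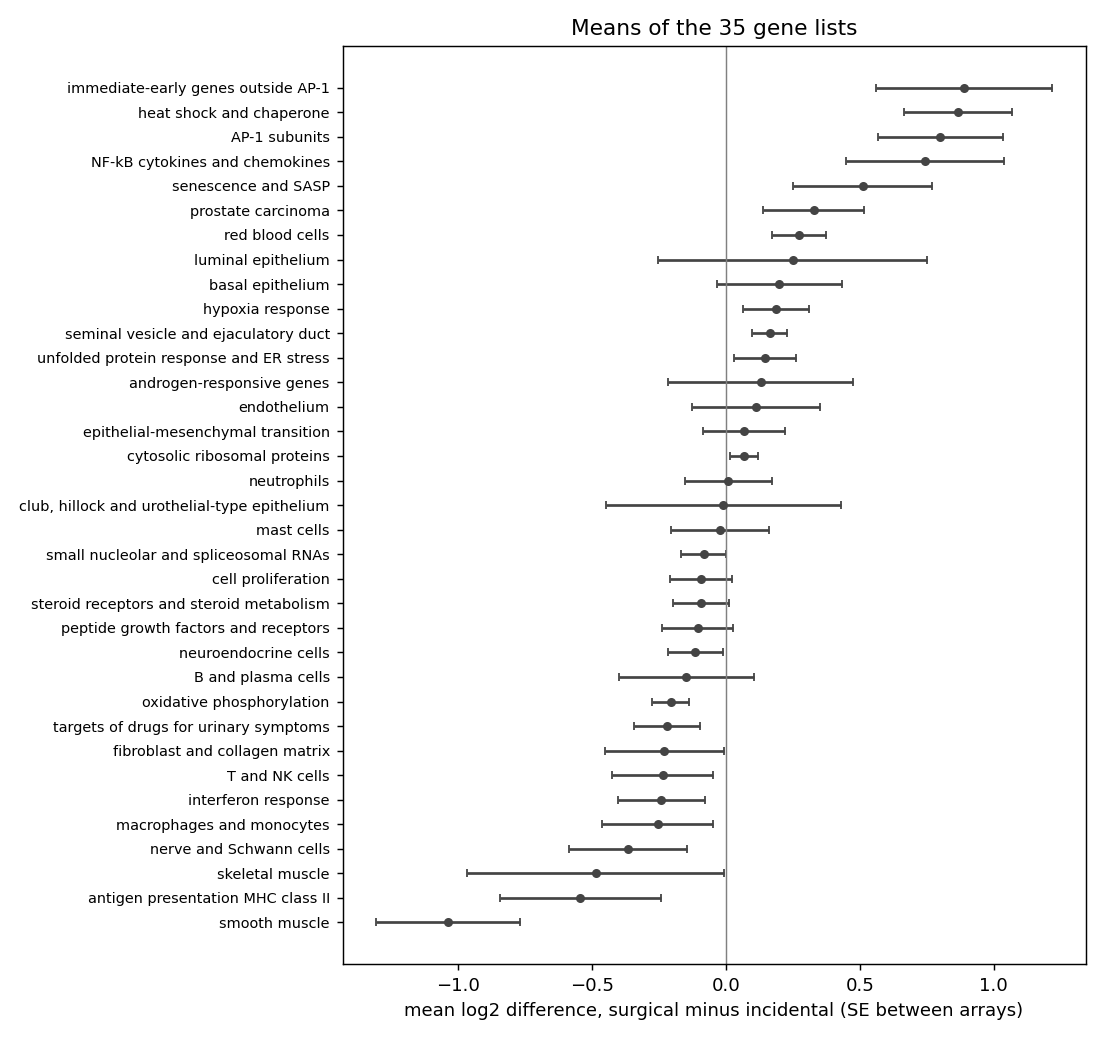
Mean log2 difference of each of the 35 gene lists, surgical minus incidental, over the measured members, with bars for the SE between the 10 surgical and 10 incidental arrays. The smooth muscle mean lay lowest at -1.04, and the immediate-early mean lay highest at 0.89.

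On principal components of all tested probe sets, the groups separated on component 2, which held 14.1% of the variance. Their means differed there by 1.38 SD (two-sided permutation test, p = 0.00022, adjusted p = 0.00066 over 3 components). They differed by 0.115 SD on component 1, with 21.7% of the variance, and by 0.109 SD on component 3, with 11.1% (adjusted p = 0.826 for each), which does not pass. On the 1000 most variable probe sets the difference on component 2 was 0.864 SD (adjusted p = 0.117), which does not pass. The mean distance between arrays, as 1 minus Pearson's r, was 0.0642 within the surgical group and 0.0486 within the incidental group, a difference of 0.0156 that was not larger than under permuted labels (two-sided permutation test, p = 0.307). Without surgical replicate 3 the difference was 0.00738, also short of the threshold (p = 0.567).

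**Figure D3:**
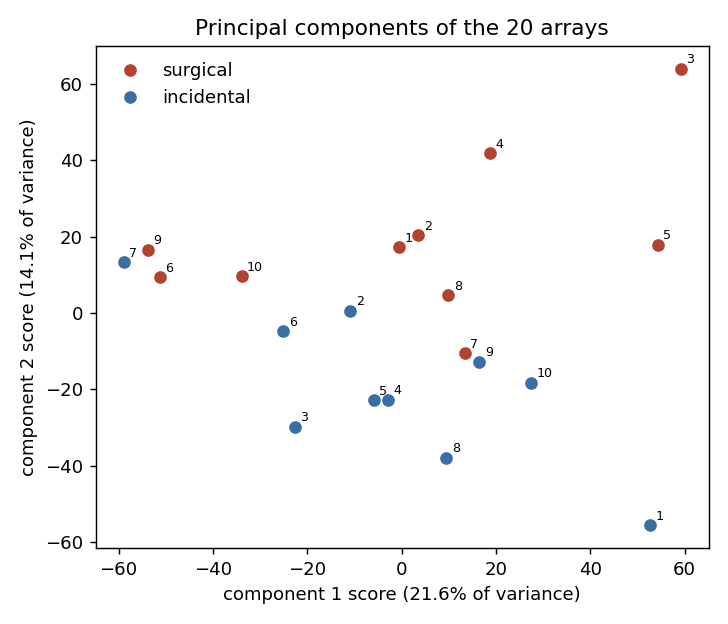
Scores of the 20 arrays on components 1 and 2, in arbitrary units, labelled by replicate number and coloured by group. Component 2 held 14.1% of the variance, and surgical replicate 3 and incidental replicate 1 lie at its opposite ends.

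The authors' deposited table lists 385 probe sets as higher and 734 as lower in a group named Group 3 against Controls, with folds of at least 1.5. Its F values and sums of squares give 21 error degrees of freedom, that is, 24 arrays in 3 groups, and the group named Group 2 was not analysed here. The table's means for Controls and Group 3 lay within 0.075 of the incidental and 0.058 of the surgical means. In the authors' deposited table, 218 of the higher and 588 of the lower probe sets had an unadjusted p under 0.05, and 0 had a step-up adjusted p under 0.05, the smallest being 0.0521. Of the listed probe sets tested here, 367 of 367 higher and 709 of 709 lower ones had the same sign. With means that close and folds of at least 1.5 the sign could not differ, so this is no independent evidence. By limma, 10 of the higher and 49 of the lower ones passed at an adjusted p under 0.05, and 219 and 588 at an unadjusted p under 0.05. The authors' deposited table gives FOSB a fold of 4.53 (p = 0.00499) and DES a fold of -2.86 (p = 5.87e-05), and limma on the deposited log2 values gave FOSB a fold of 4.58 and DES a level 2.82 times lower in surgical samples.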

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

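The further skeletal muscle genes tested were chosen after the pattern but before their own values were seen. A sample was singled out when its gap to the nearest of the other 9 arrays of its group exceeded, as a share of the group's range, Dixon's critical value for 10 samples, which happens by chance in about 5% of groups. This was met by 26 of 218 groups of values, most of them in incidental replicates 1 and 7 and surgical replicate 3.

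Incidental replicate 1 had a skeletal muscle list mean of 8.30 against at most 3.91 on the other arrays. MYL1 was at 11.63 against at most 6.12, ACTA1 at 11.36 against at most 5.56 and TNNT1 at 10.41 against at most 3.02. The same array was lowest among incidental arrays in CDH1 (6.44, next 9.56), KRT18 (3.70, next 4.93), and the means of the basal epithelium list (4.38, next 5.88) and the epithelial-mesenchymal transition list (5.85, next 6.55). It was highest in LDB3 (7.94, next 6.32), COX7B (7.30, next 6.73) and the oxidative phosphorylation mean (7.24, next 6.94). A candidate explanation is skeletal muscle in the tissue sampled: of 15 further skeletal muscle genes outside the list, 14 were highest on this array among all 20, among them KLHL41 (10.00 against at most 3.68) and TNNC1 (9.97 against at most 5.02), although MYBPC1 reached 9.66 on another array. A biological difference between the groups was not tested here, as the pattern lies in 1 array.

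Incidental replicate 7 was lowest in its group in the means of the MHC class II list (4.64, next 6.18), macrophages and monocytes (4.38, next 5.36), mast cells (4.96, next 5.88) and peptide growth factors (5.74, next 6.15), and in HLA-DQA1 (2.13), HLA-DRA (7.53) and HLA-DPB1 (6.10). It was highest in DNAJB1 (9.96, next 8.57) and HSPD1 (8.55, next 7.78). Surgical replicate 3 was highest in its array median (3.72, next 3.50) and PAX2 (4.69, next 4.22), and lowest in UQCRC1 (6.06, next 6.57) and the epithelial-mesenchymal transition mean (6.09, next 6.61).

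Single values stood apart in the nerve and Schwann cell mean of surgical replicate 5 (5.04, next 4.26), HBA2 in surgical replicate 4 (2.73, next 3.50), the ribosomal protein mean of incidental replicate 5 (6.87, next 6.68), MUC6 in incidental replicate 4 (3.93, next 3.38) and RPS23 in incidental replicate 9 (7.65, next 8.05).

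Among 31230 probe sets without a gene symbol, which the comparison of genes did not use, limma called 7 at an adjusted p under 0.05, 3 higher and 4 lower in surgical samples. The probe set named linc-SYNM-1 was at 6.14 ± 0.72 on surgical and 7.79 ± 0.58 on incidental arrays (SD, n = 10 each; adjusted p = 0.0339), and was chosen after its values were seen.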

How the results depend on the processing

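The removal of arrays standing apart, the permutation of list means, and the removal of 1 array from the comparisons of array medians and of list means were chosen after the results were seen. Of the 62 genes, all passed with workbook values, and 79 passed with trend and robust moderation, 62 of them shared. Without the 4 arrays standing apart 56 passed, of which 30 were shared, and 55 of at least 1.5-fold. Counts moved further under other settings, and for genes and for genes of at least 1.5-fold they were 17 and 14 after quantile normalization, 16 and 14 after centring on medians, 225 and 141 with the filter on dim values, 148 and 108 with array weights, 0 and 0 with luminal and smooth muscle covariates, 4 and 3 by one-way ANOVA with Benjamini-Hochberg adjustment, and 3315 and 718 by one-way ANOVA at an unadjusted p under 0.05. Limma called 0 genes at an adjusted p of 0.01, 380 at 0.10 and 3277 at an unadjusted p under 0.05. Leaving out 1 array gave from 0 to 381 genes. Thresholds change by construction, and the filter tests fewer probe sets; for the others the cause was not tested.

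The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.29 to 0.15, 2 of 10 pairs were over 0.1, and 0 of 10 arrays correlated best with its own number. With the replicate number as a block, 3 genes passed, 3 of them of at least 1.5-fold.

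Of 9 higher and 13 lower named genes past the test, 8 and 3 passed after quantile normalization, 7 and 2 after centring on medians, 6 and 6 without the arrays standing apart, 0 and 1 with the replicate number as a block, and 0 and 0 with the covariates or by one-way ANOVA, and none turned direction. With the covariates the median difference of the 9 higher genes went from 1.59 to 1.65 while the median SE of the 22 went from 0.292 to 0.372. The median difference of the 13 lower genes went from -1.50 to -0.52. DES, KCNMB1 and ACTA2 are among these 13 and belong to the smooth muscle list whose mean is a covariate. Their differences therefore shrink in part by construction. Of 35 lists, 15 passed camera, 0 with an estimated correlation, 2 by fry and 4 by the permutation of list means, namely heat shock and AP-1 higher and smooth muscle and oxidative phosphorylation lower. Other list settings gave 13 to 22. In the permutation of list means the adjusted p was 0.0479 for AP-1 and for oxidative phosphorylation. Without incidental replicate 1 the oxidative phosphorylation difference went from -0.207 to -0.165 (unadjusted permutation p from 0.00547 to 0.0118). With the covariates camera's direction turned for MHC class II (median 0.375), smooth muscle (-0.05, which is its own covariate), fibroblasts (0.41), macrophages (0.186), ribosomal proteins (-0.09), small RNAs (-0.156) and the unfolded protein response (-0.073); the cause was not tested.

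Component 2 separated the groups by 0.864 SD (adjusted p = 0.117) on the 1000 most variable probe sets and by 1.46 SD with the filter on dim values. The difference in spread stayed short of the threshold under every alternative run, from 0.00738 to 0.0228 when 1 array was left out. Of the authors' listed probe sets, 59 passed here and 807 at an unadjusted p under 0.05. Of 10 correlations of the AP-1 mean, 6 passed and 3 did so without the 2 arrays farthest from the median. Signal near the background probes, at 2.48 to 3.08 on average per array, limits what dim genes can show.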

Other observations

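All tests of explanations in this part except the counts over other splits of the arrays were chosen after the results were seen. The list named for targets of drugs for urinary symptoms does not establish that a drug in use acts on each member. Of its 22 measured genes, 4 were lower in surgical samples when adjusted over the list alone and 0 over all genes. They were ADRA1A, the alpha-1A adrenergic receptor of prostate smooth muscle (log2 difference -1.19, limma adjusted p = 0.0631 over all genes), SRD5A2, the type 2 steroid 5-alpha-reductase (-0.94, 0.0841), EDNRA, an endothelin receptor (-0.87, 0.107), and PDE5A, a cyclic GMP phosphodiesterase (-0.90, 0.173). Among 33 steroid genes, HSD17B6 (-1.10, 0.0739), SRD5A2 and CYP11A1 were lower when adjusted over the list alone. No size is given for CYP11A1, which averaged 2.73 on surgical arrays, below the mean of 2.86 of their background probes. Smooth muscle genes were lower on the same arrays, with a list mean difference of -1.04. With the luminal and smooth muscle list means as covariates the difference was 0.02 for ADRA1A, 0.25 for PDE5A, -0.33 for SRD5A2, -0.23 for EDNRA and -0.46 for HSD17B6, none of which passed. These genes were chosen after their values were seen.

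Within each group, the AP-1 mean was set against 5 other list means, 10 relations in all, with permutation p-values adjusted over the 10. It followed the immediate-early mean in the surgical group (r = 0.992, p = 1e-05, the smallest the permutations can give, adjusted p = 5e-05, rho = 0.988, p = 1e-05), with r = 0.961 without the 2 arrays farthest from the median AP-1 mean. It did so in the incidental group too (r = 0.986, p = 1e-05, adjusted p = 5e-05, rho = 0.952, p = 0.00013), with r = 0.98 without them. It followed the NF-kB mean in the incidental group (r = 0.937, p = 0.00011, adjusted p = 0.000367, rho = 0.952, p = 0.0001), with r = 0.956 without them. In the surgical group the relation with the NF-kB mean (r = 0.863, p = 0.00215, adjusted p = 0.0043, rho = 0.673, p = 0.0396) passed only with those 2 arrays, with r = 0.495 and p = 0.213 over the other 8. The relation with the heat shock mean (r = 0.846, p = 0.00177, adjusted p = 0.0043, rho = 0.842, p = 0.00357) stayed above 0 but no longer passed over those 8 arrays (r = 0.631, p = 0.0841). In the incidental group the AP-1 and heat shock means had r = -0.032 (p = 0.935, adjusted p = 0.935, rho = 0.115, p = 0.761), and r = 0.693 without them (p = 0.0659). The difference between the groups in this relation was not tested. The luminal mean went against AP-1 in the incidental group (r = -0.697, p = 0.0188, adjusted p = 0.0313, rho = -0.721, p = 0.0237), and stayed below 0 but no longer passed over 8 arrays (r = -0.568, p = 0.113). Fewer arrays and a narrower range of the AP-1 mean weaken such a test by construction. In the surgical group it had r = -0.435 (p = 0.207, adjusted p = 0.23, rho = -0.394, p = 0.264) and r = -0.12 without them. Smooth muscle had r = 0.495 (p = 0.145, adjusted p = 0.181, rho = 0.248, p = 0.492) in the surgical and r = 0.606 (p = 0.0636, adjusted p = 0.0909, rho = 0.515, p = 0.135) in the incidental group, and r = -0.33 and 0.595 without them.

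The mean over the 68 heat shock, immediate-early and AP-1 genes was 0.86 higher in surgical samples (SE 0.259, permutation p = 0.00532). A lower share of smooth muscle is argued against but not excluded. With the smooth muscle mean as a covariate the difference was 1.37 (permutation of residuals, p = 0.00045), and the slope within groups was 0.492. The adjustment extends this slope over a group difference of -1.04 in the covariate. In the surgical group the AP-1 relation with smooth muscle went from r = 0.495 to -0.33 without the 2 arrays farthest from the median AP-1 mean. The arrays standing apart are argued against as the whole source by a difference of 0.80 without them (permutation p = 0.0226). Hypoxia of the tissue stays open, since the hypoxia mean differed by 0.19 (SE 0.123, permutation p = 0.151) with 13 members above 0 and 7 below. Stress while the tissue was removed and handled may contribute and cannot be told apart from the surgical distinction, because the labels record no handling; the pooled within-group r of AP-1 and heat shock means (0.636, permutation p = 0.00822) decides nothing, being 0.846 in the surgical and -0.032 in the incidental group. A biological difference between surgical and incidental BPH stays open, as untested.

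The smooth muscle mean was 1.04 lower in surgical samples, a difference of -1.04 (SE 0.269, permutation p = 0.00112). Arrays standing apart are argued against by a difference of -1.09 without them (permutation p = 0.00278). A lower share of smooth muscle among otherwise unchanged cells would raise the lists of other cell types alike, and the differences of 7 such lists ran from -0.37 to 0.25 with 3 above 0 and a mean of -0.08 (permutation p = 0.374), or from -0.27 to 0.20 with 2 above 0 without incidental replicate 1. Their SD of 0.253, or 0.166 without that array, was not beyond that under permuted labels (p = 0.432 and 0.71), so a changed share and lower expression per cell cannot be told apart, the spread between arrays being too wide to decide. A biological difference between the groups stays open, as untested.

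Among 100 splits of the 20 arrays into 10 and 10, 1 gave as many as the 62 genes, the real one. The same held for the 58 of at least 1.5-fold, and the highest other split gave 9 in each case. Chance is argued against for both counts, but 100 splits cannot exclude it. At an unadjusted p under 0.05 the real split gave 3302 probe sets, 3 of the 100 splits gave as many, and the highest other gave 3909. Chance is not argued against for the 15 lists that camera called at a preset correlation, since 52 of the 100 splits gave as many and the highest other gave 24.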
